A study of Drosophila melanogaster with 3 samples.

How the data were processed

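DNA adenine methyltransferase identification (DamID) was measured on 3 tiling arrays of the Drosophila melanogaster genome. In this method a bacterial DNA adenine methyltransferase, Dam, is fused to a chromatin protein and marks GATC sites near where the protein sits, and Dam expressed alone gives the background of accessible DNA. Each array held methylated DNA from embryos with a UAS transgene for Dam fused to Ci m1-m4 in one dye and methylated DNA from embryos with UAS Dam alone in the other. Ci (cubitus interruptus) is the zinc-finger transcription factor of the Hedgehog pathway, and the series title calls this form the activator. Per the labels' growth protocol, embryos were collected over 2 h and aged for a further 4 h, while the extraction protocol gives an age of 2 to 6 h. DamCi DNA carried Cy5 on replicates 1 and 3 and Cy3 on replicate 2. For replicate 3 the labels disagree about channel 1, whose source name gives Dam alone while its genotype field gives DamCi. The source name was followed. Nothing in the labels says whether the replicates came from separate embryo collections, so p-values measure the spread between these 3 arrays, which may be technical.

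The deposited scanner files hold one spot intensity per probe and dye, extracted with NimbleScan and neither background-corrected nor normalized, per the file headers and the values. The design name in the headers describes 60-mers, and the median spacing of the tiled probes was 300 bp. Each array had 377566 tiled probes on the arms 2L, 2R, 3L, 3R, 4 and X, 1434 random control probes, and 6000 further spots that each name a tiled probe. The random and further spots were left out of the comparisons. The authors also deposited a table of normalized log2 ratios per probe, and the submitters' processing notes name R 2.7.1 and limma without giving the steps. Set against the scanner intensities, each column of that table ran Cy5 over Cy3, with correlations of 0.937, 0.935 and 0.967 with the unnormalized ratios. Against a limma loess fit of the same intensities with no further centring, over the tiled probes, the slope was 1.00002 to 1.00004 and the median absolute difference 0.00037 to 0.00069 on the 3 arrays, so its scale is log2 and its centring that of loess. The genome build is not given in the sources used here.

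Coordinates are those of the array files, counted from 1. The gene table at hand is of Release 6, and on 5 of the 6 arms it places genes beyond the last probe. A shared build was thus not established, and no gene, exon or motif was assigned. The gene values, gene list tests and search for the Ci binding site in the design were therefore not made, and regions are named by position alone. The gene lists fixed before the data were examined were not used for the same reason.

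For each probe the log2 ratio of DamCi over Dam alone was taken from the intensities as given, with the sign turned by the dyes in the labels, and each array was centred on the median of its tiled probes. A value of 0 is thus the typical probe, and a genome-wide shift of DamCi over Dam alone cannot be seen. No loess was applied, since many probes may truly shift, and loess was an alternative. The mean over 3 arrays was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05 over all tiled probes. The spread used is mostly pooled across probes, with 11.6 prior degrees of freedom for probes and 9.2 for windows against 2 residual ones. For regions, the ratios of all probes within 750 bp of each probe were averaged per array, with at least 3 probes, and these window means were tested in the same way. A window passed with an adjusted p under 0.05, a mean of at least 0.5 in size and the same sign on all 3 arrays. Passing windows of one direction within 1000 bp were merged. A region's edges are the centre probes of its outermost passing windows, and its ratio is the mean of the probes between them. A window reaches 750 bp past its centre, so a region can take in unchanged probes at its edges. Its mean then understates the ratio inside, and the named regions, ranked by their means, stood in another order by their inner probes. Of the regions, 1294 higher and 1679 lower ones rest on 1 window, and in 116 higher and 270 lower regions the mean of the probes inside had the opposite sign to the window mean.

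The named regions follow a rule set before the data were examined, namely the 10 highest and 5 lowest means among called regions with at least 5 passing windows. Background was the 95th percentile of an array's random probes. The number of arrays limits the precision. On simulated ratios of 377566 probes, drawn with limma's moderated spread of these arrays, no probe and no region was called when nothing changed. With 200 changed blocks of 10 probes, the region call recovered 74.6% of blocks changed by 0.5, and 100% of those changed by 1 and by 2. Of the 212 regions called in that simulation, 24 lay away from the changed blocks. The test on single probes called 1.19% of the probes changed by 0.5, 45.1% of those changed by 1 and 100% of those changed by 2. Alternatives covered normalization, background correction, the dye term, the variance prior, dim probes, window width, size, merging, threshold and leaving out each array.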

Results

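The series asked where the activator form of Ci, the Hedgehog pathway's transcription factor, binds in the Drosophila embryo. It comprised 3 arrays with 2 dyes, each setting DNA methylated by DamCi m1-m4 against DNA methylated by Dam alone, so the design holds 1 comparison with n = 3. The median tiled signal in the DamCi channel was 565, 773 and 899 on replicates 1, 2 and 3, against random-probe medians of 118, 176 and 122. In the Dam alone channel it was 1814, 1954 and 2087, against random-probe medians of 453, 165 and 188. Between 81.1% and 91.4% of tiled probes lay above the 95th percentile of the random probes, and at most 0.0818% of tiled probes were saturated in any channel.

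The ratio of DamCi to Dam alone differed from that of the typical probe over a large part of the tiled genome. At 42678 probes, 11.3% of those tested, the ratio was higher in DamCi, and at 53588 probes, or 14.2%, it was lower (limma, adjusted p under 0.05). Merged windows gave 7869 regions higher in DamCi, covering 13.0 Mb, and 10823 regions lower in DamCi, covering 15.6 Mb. Of 376888 windows, 13.1% lay in higher and 15.6% in lower regions. Leaving out replicate 3 reduced the lower probes to 34909. The centred ratios also carried a trend with signal that differed by array. Their correlation with the Dam alone level of other arrays was -0.34 to -0.22 on replicates 2 and 3. On replicate 1 it was 0.09 and 0.10, and after loess it was -0.21 to -0.15 over the 3 arrays. The ratio was correlated between neighbouring probes on different arrays, with a mean r of 0.48 ± 0.02 (SD, 3 pairs of arrays) at 300 bp, 0.20 ± 0.01 at 1500 bp and 0.10 ± 0.01 at 6000 bp, against 0.73 ± 0.06 at the same probe.

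The 3 arrays ran alike once their ratios were turned by the labelled dyes. Read as Cy5 over Cy3, replicate 2 correlated with replicates 1 and 3 at r = -0.66 and -0.78, while replicates 1 and 3 correlated at 0.74. Turned to DamCi over Dam alone, the correlations across 377566 probes were 0.66 for replicates 1 and 2, 0.74 for replicates 1 and 3 and 0.78 for replicates 2 and 3, with Spearman's rho of 0.51, 0.58 and 0.71. Probes are not independent replicates, and no p-value was attached to these values. Replicate 3, whose channel 1 labels disagree, thus ran with replicates 1 and 2 when its source names were followed. Exchanging DamCi and Dam alone on every array would leave these correlations unchanged. They therefore do not show which channel held DamCi, for which the labels were relied on. Within an array the DamCi and Dam alone signals were themselves correlated, at r = 0.87, 0.85 and 0.88.

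**Figure D1:**
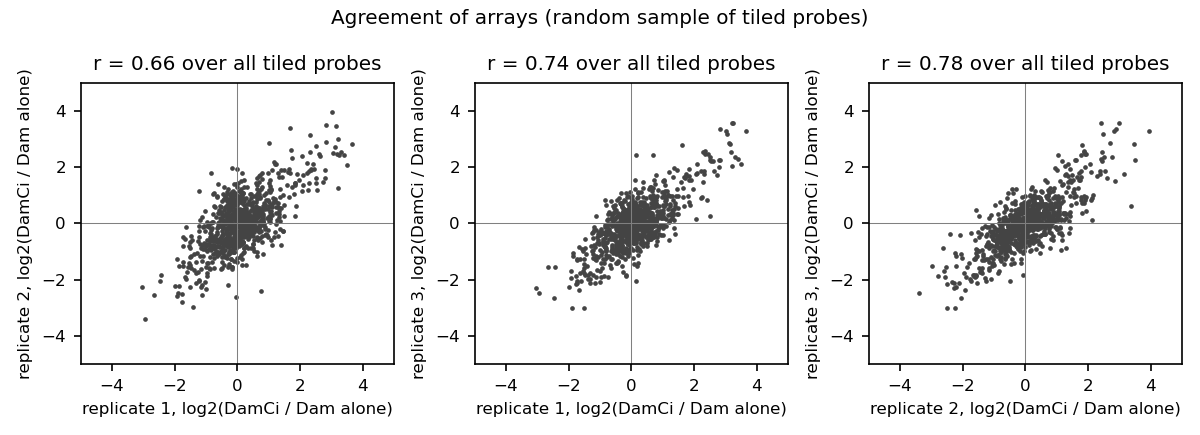
Log2 ratio of DamCi over Dam alone on each pair of the 3 arrays, 1 point per probe for a random sample of tiled probes, with both axes on the log2 scale. In each panel the points rise together, and the correlation over all tiled probes is 0.66, 0.74 or 0.78.

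Regions higher in DamCi were the fewer, and more of them were long or had a log2 ratio of 2 or more in size, while the lowest named region exceeded every higher named region in size. The median length was 989 bp for higher and 985 bp for lower regions. Above 10000 bp there were 88 higher and 28 lower regions, and the longest measured 33955 bp and 18397 bp. In higher regions the median log2 ratio was 0.72 for those of up to 1000 bp and 1.73 for those above 10000 bp. In lower regions the corresponding medians were -0.77 and -0.99. A stronger peak passes the size minimum further out, and edge probes weigh more in a short region. Some rise of size with length is thus built into the call. Among regions with at least 5 passing windows, 175 had a mean log2 ratio of 2 or more and 8 a mean of -2 or less, and after loess within arrays these numbers were 59 and 8. Over all alternatives run, these numbers ranged from 48 to 600 for higher and from 5 to 31 for lower regions. Merging windows over 3000 bp turned the order of the long regions, with 317 higher and 359 lower regions above 10000 bp, and without replicate 3 there were 87 and 6.

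**Figure D2:**
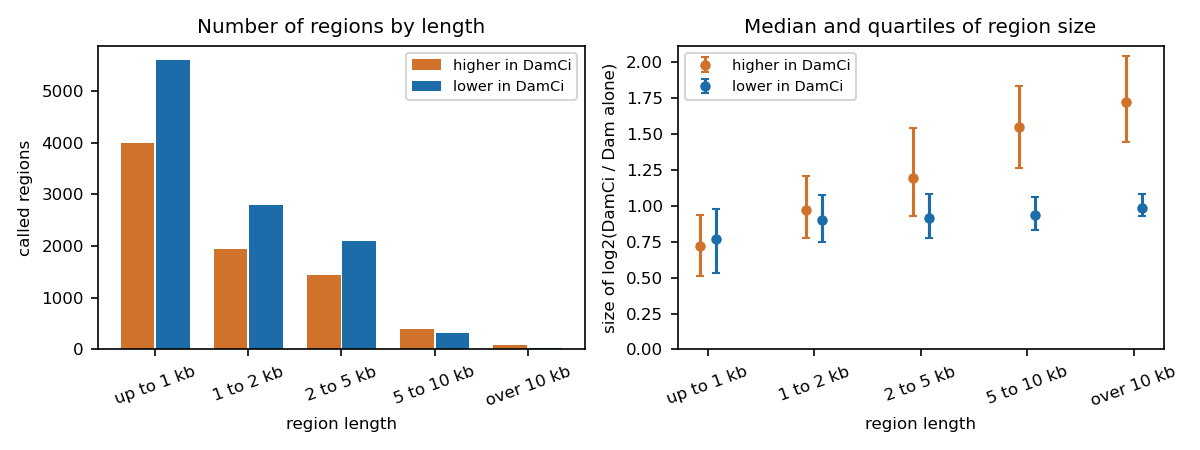
Left, the number of called regions by length class, higher and lower in DamCi, as bars. Right, the size of the regions' log2 ratio by length class, with points at the median and bars from the lower to the upper quartile. The medians of higher regions run from 0.72 to 1.73, and those of lower regions from 0.77 to 0.99 in size. Some rise with length is built into the region call.

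The highest mean of a named region lay on 2R at 9074119 to 9088278, 7.79-fold above the typical probe with a log2 ratio of 2.96 ± 0.22 (SD, n = 3). Next came a stretch of 24326 bp on 3L at 14921253 to 14945578, with 2.95 ± 0.16. These differed by less than the spread between arrays. Of 17 alternatives, 10 moved the ratios, and in 8 of those the region on 2R was not the highest of the 10, ranking as low as 5. By the upper quartile of the probes inside, the highest of the 10 was the region on 3L at 11315852, with 4.10 (SD 0.21). The region on 2R at 9074119 had 3.73 (SD 0.33) by this measure. In the stretch on 3L, 4 probes were at background in Dam alone on all arrays and 3 in DamCi. With Dam alone set to at least background, its ratio was 7.49-fold. On 3L at 15976642, with 1 such probe in each channel, it was 6.26-fold. A probe dark in both channels gives no bound, so these are not strict lower limits. A region on 2L at 2179801 to 2184662 followed at 2.87 ± 0.22, and one on 3L at 11315852 to 11319511 at 2.77 ± 0.21. The region on 2R at 17051430 to 17054790 reached 2.73 ± 0.16, and that on 3L at 15976642 to 15988677 reached 2.67 ± 0.13. The other 4 of the 10 highest lay on 2L, starting at 19212602, 19150538, 20460935 and 4362937, with log2 ratios of 2.62 ± 0.24, 2.60 ± 0.13, 2.59 ± 0.31 and 2.59 ± 0.24. Every passing window in these 10 regions had an adjusted p of 0.0217 or less (limma). Saturated probes, whose signal the scanner limit understates, numbered 1 to 7 in 7 of the 10 regions. No region of X, 3R or chromosome 4 was among these 10.

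In the 10 highest regions the DamCi signal rose above that of the 5000 bp on either side, while the Dam alone signal moved less and in both directions. In the region on 2R at 9074119, DamCi stood 4.23 ± 0.15 log2 units above its flanks and Dam alone 1.18 ± 0.34 (SD, n = 3). Its left flank holds a region lower in DamCi, at 9071424 to 9073590 with a log2 ratio of -2.11 ± 0.19, and without the 4 flank probes at -2 or less, left out after their values were seen, these rises were 4.26 ± 0.11 and 1.83 ± 0.35. In the region on 3L at 15976642 the values were 4.10 ± 0.12 and 1.56 ± 0.09. In the region on 2L at 20460935 DamCi was 1.29 ± 0.37 above and Dam alone fell by 0.54 ± 0.05 relative to the flanks. Dam alone was higher inside than outside in 6 of these 10 regions and lower in 4. With every flank probe of 2 or more in size left out these numbers were the same, and DamCi stood 2.02 to 4.26 above its flanks.

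**Figure D3:**
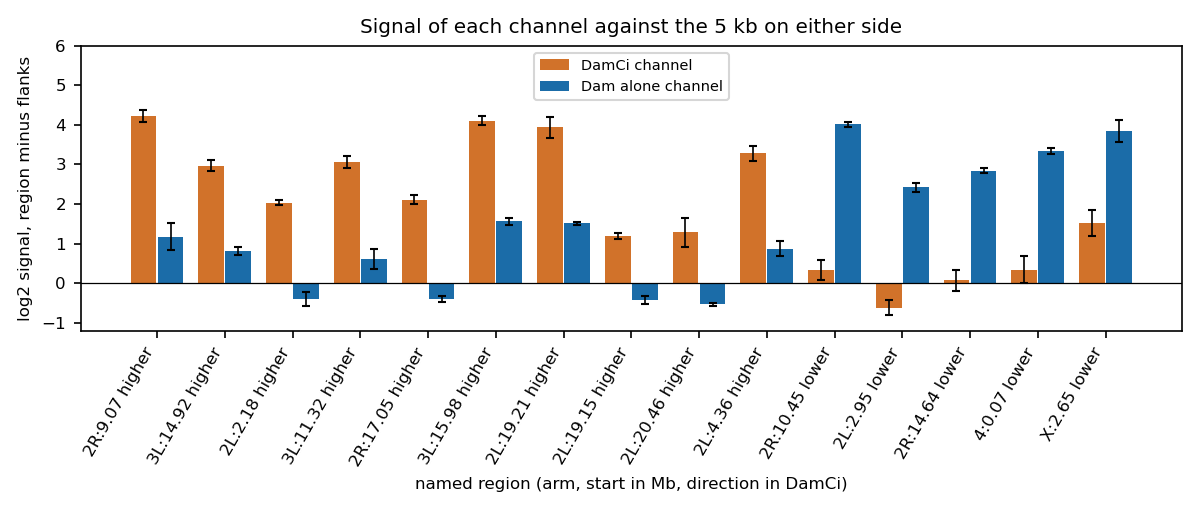
Difference in mean log2 signal between each named region and the 5000 bp on either side, as bars for the DamCi and the Dam alone channel, with error bars of 1 SD over 3 arrays. DamCi rises in the 10 higher regions, and in the 5 lower ones Dam alone rises by 2.42 to 4.01.

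The lowest mean of a region lay on 2R at 10451721 to 10455382, with a log2 ratio of -3.62 ± 0.27 (SD, n = 3). There DamCi was 12.3-fold below Dam alone relative to the typical probe. Its first probe had 0.09, 0.12 and 0.53 on replicates 1, 2 and 3, and that at 10454437 had -5.91, -6.58 and -6.53. The mean thus includes edge probes and understates the fall inside. With dim probes left out, this region had -3.62 and that on 2L at 2947837 had -3.60, closer than the spread between arrays. By the lower quartile of the probes inside, these regions had -5.14 (SD 0.25) and -5.25 (SD 0.41), so their order turned within the spread. Regions on 2L at 2947837 to 2953000 and on 2R at 14636724 to 14640378 had log2 ratios of -3.19 ± 0.08 and -3.15 ± 0.22. Those on chromosome 4 at 68101 to 73561 and on X at 2645722 to 2649983 had -2.76 ± 0.46 and -2.42 ± 0.54. Passing windows in these 5 regions had adjusted p-values of 0.0104 or less (limma). Here it was the Dam alone signal that stood out, with a rise above the flanks of 4.01 ± 0.07 in the first region, 2.42 ± 0.11 on 2L, 2.84 ± 0.06 in the other region on 2R, 3.33 ± 0.07 on chromosome 4 and 3.84 ± 0.28 on X. The DamCi signal differed from its flanks by 0.33 ± 0.25, -0.62 ± 0.19, 0.08 ± 0.27 and 0.34 ± 0.34 in the first 4 of these, and by 1.51 ± 0.33 on X. A lower region with a log2 ratio of -2.29 ± 0.24, starting at 14643332, reaches into the flank of the region on 2R at 14636724. With flank probes of 2 or more in size left out, Dam alone rose by 2.42 to 4.21 and DamCi differed by -0.62 to 1.71. In each of the 5 regions, 3 to 7 probes were saturated in at least one channel and array, at which the scanner limit understates the signal. The regions on 2L and on 2R at 14636724 each had 2 DamCi probes at background on all arrays, and 2 and 1 in Dam alone. With DamCi set to at least background, the ratio was 8.48-fold and 8.55-fold lower in DamCi. A probe dark in both channels gives no bound, so these are not strict lower limits.

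**Figure D4:**
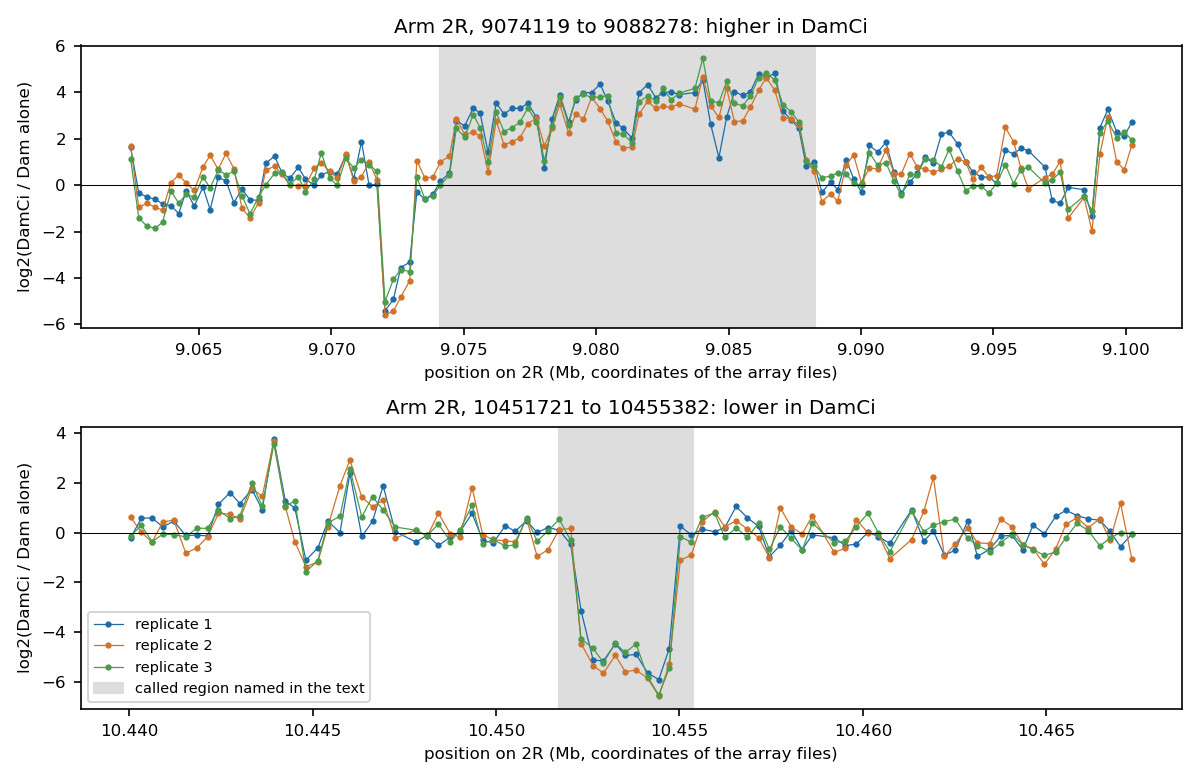
Log2 ratio of DamCi over Dam alone per probe on 2R, with 1 line per array and position in Mb. Shaded are the named regions with the highest (top) and the lowest (bottom) mean. The 3 arrays run together in both, with means of 2.96 and -3.62 over the shaded probes, and left of the highest region lies a lower one from 9071424.

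The longest region higher in DamCi spanned 33955 bp on 2R, from 4141843 to 4175797, with a log2 ratio of 2.36 ± 0.30 (SD, n = 3). It was followed by 2L at 7290040 to 7317360 with 2.09 ± 0.20 and 2L at 3813902 to 3838260 with 2.05 ± 0.16. On 2L at 15306316 to 15330660 the log2 ratio was 1.98 ± 0.12. The longest region of 3R, at 21834902 to 21857761, had 2.52 ± 0.25. The longest region lower in DamCi lay on 3L at 3233104 to 3251500 and had a log2 ratio of -1.16 ± 0.15, and the next on 2L at 1902629 to 1917961 had -1.10 ± 0.23. These longest regions were picked after their values were seen.

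Chromosome 4 stood below the other arms. Its mean log2 ratio was -0.18 ± 0.05 (SD, n = 3), which differed from the mean of the other arms by -0.20 ± 0.09, and it was negative on 3 of 3 arrays. Of 10000 random blocks of 3654 neighbouring probes on the other arms, 0.41% had a mean as low. These blocks overlap one another, so the share rests on far fewer separate stretches and is approximate. On chromosome 4, 8.03% of windows lay in higher regions and 23.9% in lower ones. On the other arms the shares ran from 12.8% to 13.4% for higher and from 12.7% to 17.0% for lower regions. The X chromosome, whose mean of 0.06 ± 0.02 differed from that of the other arms by 0.045 ± 0.053, less than its spread, had slightly more windows in higher than in lower regions, at 13.4% and 12.7%, and the autosomal arms 2L, 2R, 3L and 3R had more in lower ones. Set against the other arms on the same array, the means of 2L, 2R, 3L and 3R differed by 0.025 ± 0.009, -0.023 ± 0.023, -0.019 ± 0.005 and -0.014 ± 0.017. With 3 arrays a two-sided exact sign permutation test allows no p below 0.25, and the differences between arms were not tested across arrays.

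**Figure D5:**
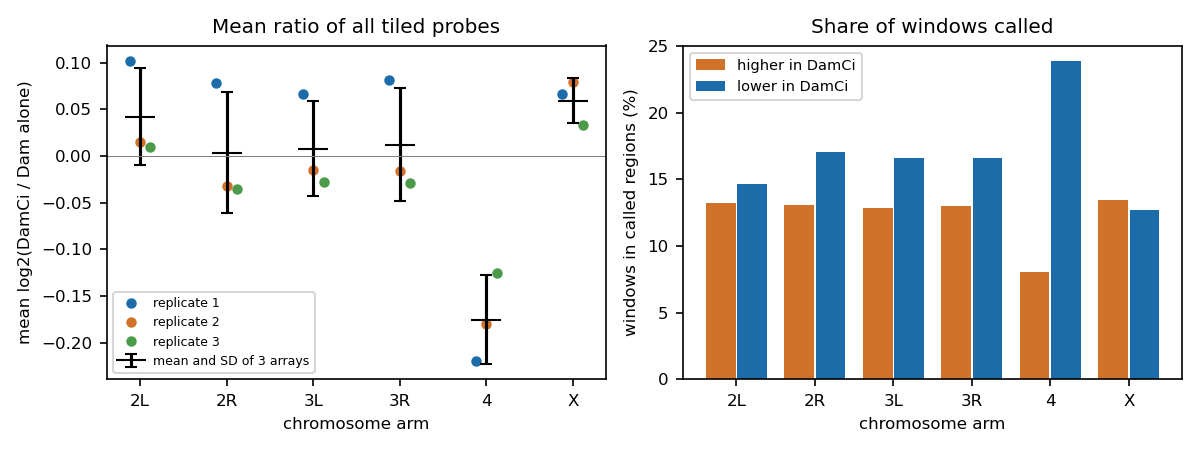
Left, mean log2 ratio of DamCi over Dam alone per chromosome arm, with a point per array and the mean with 1 SD of 3 arrays. Right, bars for the share of windows in regions higher and lower in DamCi; chromosome 4 has 8.03% and 23.9%.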

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

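Chosen only after the results they bear on had been seen were the tests of the further spots, of dye effects, of loess on chromosome 4, of the Dam alone signal, of the gaps in rank and of the sharp ends; the tests of background signal, of the chromosome 4 median and of the channel assignments were set before theirs.

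The 6000 spots outside the comparison, each of which names a tiled probe, carried signal too. Of these, 1541 passed the limma test, 689 higher and 852 lower in DamCi. Of the 1434 random probes 0 passed, with 18 higher and 1 lower at an unadjusted p under 0.05, and after loess 12 higher and 2 lower passed. Each set was fitted and adjusted on its own. The random probes' centred medians differed between arrays, at -0.23, 1.21 and 0.46, which widens the spread. Their 0 is therefore no control for the further spots. Averaged over the 3 arrays, the ratios of the further spots correlated with those of the tiled probes they name at r = 0.95, with an SD of the difference of 0.27 log2 units.

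The first pattern is the set of 5 lowest regions, which rest on a high Dam alone signal. DNA missing from the DamCi line over the whole block was argued against, since 5.13% of the probes had a DamCi signal at background on all 3 arrays. The rise of Dam alone made up 113.5% of the fall (SD 31.3 over 5 regions), which restates that high signal, so extra copies of the stretch in the Dam alone line cannot be told apart from strong methylation by Dam that DamCi lacks. A competing reading, the end of a graded distribution of lower regions, met its bound as reported, with a widest gap of 0.43 log2 units between neighbouring ranks from the first to the sixth, against at most 0.5. It is left undecided only by a rule chosen after the values were seen, that all settings must agree, since the gap was 0.67 with dim probes left out, the 1 of 8 alternatives above the bound. Sharp ends did not decide it, with a median of 10.0% of probes at intermediate ratios against 18.7% in the 10 highest regions.

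The second pattern is the lower ratio over chromosome 4. A dye bias that depends on signal was argued against, since after loess 0.06% of random blocks had a mean as low. A few extreme regions were argued against as the whole cause, since 1.80% of 1000 random blocks had a median as low, close to the 2.5% that bounded the test. As the random blocks overlap, both shares are approximate, and the share for the median lies too near its bound to be firm. Base composition and repeats were not tested, and weaker methylation by DamCi than by Dam alone on this chromosome is an open hypothesis.

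The third pattern is the number of called regions. Reading every array as Cy5 over Cy3 gave 0 regions in either direction, with 906 higher and 535 lower probes at an unadjusted limma p under 0.05. That reading turns replicate 2 alone against the labels. No window called as labelled could pass it, so its 0 decides nothing about these windows. Read so, however, replicate 2 correlated with replicates 1 and 3 at r = -0.66 and -0.78. These values argue against a dye effect shared by all arrays as the main source of the ratios. A dye bias that depends on signal was argued against as the whole cause for lower regions, of which 91.3% were overlapped by a region of the same direction after loess. For higher regions the share was 88.6%, under the bound of 90%, so for the remainder such a bias cannot be told apart from binding. The number of regions after loess was 7841 higher and 10630 lower. Exchanging the channels on every array only swaps the directions and was not counted as another assignment. Of the 4 ways then left to assign the channels, 1 gave as many calls, the labelled one. It had 42678 higher and 53588 lower probes and 7869 higher and 10823 lower regions, against 0 for each as the highest of the others. The assignments are too few for a share under 0.05. The others turn the sign of 1 array, so no window called as labelled could pass them.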

How the results depend on the processing

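The alternatives were planned, except those for the clustering of strong regions, the gaps between the lowest regions, the flanks of named regions and the adjustment over 3 tests, chosen after seeing the data. The 15 named regions kept their direction under the 10 of 17 alternatives that moved their ratios, and at least 50% of their windows passed under all 17, of which no size minimum and wider merging cannot end a call. Chromosome 4 stayed below the other arms by -0.24 to -0.15 in the 9 of 11 that moved its value. Of the 61 alternative values of the counts and of the agreement between arrays, 53 stayed within 1.5 times the reported count or within the spread. At an adjusted p of 0.01, 33164 probes were lower. With windows of 500 bp on each side 11841 regions were higher, and with 1500 bp there were 3946 higher and 5742 lower regions. A size minimum of 1 left 3451 higher and 4132 lower regions. The mean correlation between arrays moved from 0.725 to 0.819 for window means. Leaving out one array gave 34909 to 59213 lower probes, 34108 to 48038 higher probes, 6927 to 9580 higher and 9476 to 12298 lower regions; the lowest numbers came without replicate 3. In these fits of 2 arrays, as in the main fit, the spread is largely borrowed across probes. A stricter threshold or size passes fewer windows by construction, and the causes of the other changes were not tested. The authors' values gave 8063 higher and 10468 lower regions, and 89.6% and 90.1% of the reported ones were overlapped. No gene, gene list or motif alternative was run, since no annotation or sequence of the arrays' build was used here. Dim probes limit low ratios, and they can carry an offset that differs between arrays. Random probes had centred median ratios of -0.23, 1.21 and 0.46 on replicates 1, 2 and 3, thus above 0 on replicates 2 and 3.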

Other observations

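The tests here were set before their values were computed but after the list of strongest regions had been seen, and a different ranking, distance and length matching for the clustering test were chosen after its result. There were 3 tests in all, with Benjamini-Hochberg adjustment over the 3, in which the void test of neighbouring lower regions counts with a p of 1, a choice made after its value was seen.

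The 189 higher regions with a mean log2 ratio of 2 or more lay partly in groups. The richest stretch, on 3L from 14907123 to 15013702, held 4 such regions with 49151 bp in them and included the named region on 3L at 14921253. Stretches on 3R at 25077640 to 25138589 and at 21820540 to 21867097 held 3 regions each, with 46343 bp and 39458 bp in them. Others with 3 lay on 2R at 15544819 to 15614793, on 2L at 3539135 to 3606360 and at 5381101 to 5402760, and on 3L at 14112752 to 14162873. In all there were 27 groups of at least 2 such regions, each within 50000 bp of the next, and 127 regions lay alone.

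A hypothesis is that strong regions lie near each other more often than other higher regions of like length. Of the 189, 32.8% had another within 50000 bp, against a median of 21.2% in 10000 redraws among higher regions of the same of 4 length classes (one-sided permutation p = 0.0027, adjusted 0.0081). Ranked by ratios after loess, the share was 33.9% against 20.6%, with 129 regions shared, and within 20000 bp it was 22.2% against 10.6% (one-sided permutation p = 0.0015 and 0.0005, the latter the smallest that 2000 redraws can give). Of the 189, however, 159 lay in the longest of the 4 classes, and the redrawn regions were shorter, with a median of 2776 bp against 4244 bp. Redrawn within 40 length classes, with a median of 3975 bp, 24.3% had another within 50000 bp (one-sided permutation p = 0.0255, not adjusted). Part of the excess thus went with length. Under the adjustment used for the first p, the p from these finer classes would not pass 0.05. Whether strong regions group beyond what their length gives was thus left undecided. Several binding stretches around one gene may be a source of such grouping, which was not tested, and so may strong regions split by a few failing windows.

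Whether lower regions lie beside higher ones more often than by position alone stayed undecided. A lower region lay within 2000 bp of 35.1% of higher regions, against a median of 44.9% in 1000 circular shifts. After shifting, however, 19.7% of lower regions overlapped a higher one, which called regions cannot do, so the shifts set too high a level and exclude nothing.

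A further hypothesis is that the ratio differs near the centromere. The 1000000 bp nearest to it on the 5 large arms had a mean log2 ratio of -0.046. This lay just below the 2.5th percentile of random blocks at -0.041 (two-sided permutation p = 0.0382, adjusted 0.0573). It thus did not pass 0.05 under the adjustment used here. With the void test at its computed p, or over the 2 valid tests alone, the adjusted permutation p was 0.0382. Whether it passed thus rested on a choice made after the values were seen. Over the 3 arrays the mean log2 ratio was -0.062, -0.082 and 0.0070 (SD 0.047), so it was below 0 on 2 of 3. The arms did not go together, with -0.13 on 2R, -0.15 on 3L, -0.06 on X, -0.0019 on 2L and 0.11 on 3R.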
